A study of Ictidomys tridecemlineatus with 5 samples.

How the data were processed

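Ocular RNA of the ground squirrel was measured by RNA sequencing in 2 eye libraries and 3 retina libraries, grouped by the tissue in their titles. Per the labels' protocols, each library preparation pooled RNA of 4 animals. Each tissue has a table of its own, with a value, a length and a best hit per assembled transcript, and a table of Swiss-Prot hits, per the file headers. Bowtie is named in the submitters' processing notes with no version. The assembler and the mode of counting are not given in the sources used here.

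The deposited values were read as RPKM, from the values themselves, because the file headers call them expression values only. The value times the transcript length was a whole multiple of 1 constant in each table, within 0.01 reads, for 100% of transcripts. That constant corresponds to a total of 264219334 reads for eye and 355988270 for retina, the total behind the scaling by the authors. At 1 RPKM a transcript of 1000 bases then has 264 reads in eye (95% Poisson interval 233 to 298) and 356 in retina (320 to 395). Reads recovered in this way summed to 5077626712 over eye transcripts and 3745035688 over retina transcripts, 19.2 and 10.5 times those totals. Reads counted on several transcripts each would give this, and so would scaling to a total other than that of mapped reads, and neither was tested. The totals are per tissue and not per library.

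Transcripts were joined across the tables by the Swiss-Prot entry name before the species code. The design fixed before the data were examined used the sum over the transcripts of a protein, rescaled to an equal total in both tissues. Because sums would count reads repeatedly if these recur across transcripts, the main level used here is the RPKM of the highest transcript of each protein, with no rescaling beyond that of the authors. Both changes depart from the design, and they were made after values by both measures had been seen. The counts by the designed measure stand beside the main counts. Of the highest transcripts behind the 13383 proteins compared, 1.23% in eye and 1.56% in retina were under 200 bases, but this includes several of the most abundant names. Over all transcripts, 57.8% in eye and 51.3% in retina were under 200 bases. They held 99.0% and 98.2% of the RPKM summed over all transcripts.

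Differences are log2(eye RPKM + 1) minus log2(retina RPKM + 1), for proteins in both tables at 1 RPKM or more in either tissue. The tissues were assembled and normalized separately and have 1 value each, so no test was run. A protein was called higher at a 2-fold difference, a mark chosen after seeing the data. The 28 gene lists were fixed before the data were examined. The median of a list's members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level with seed 7, as a description of these libraries. A list was called outside the random lists below percentile 2.5 or above 97.5, also chosen after seeing the data. A gene's level is the highest over its Swiss-Prot names, and a protein in 1 table only has no difference. Counting intervals at 95% came from random draws around the recovered reads for differences and from the Poisson variance of the logarithm for ratios. They treat reads as independent and cover counting error only.

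The genes named were chosen by rules written beforehand: up to 4 members per list with the highest mean level, the 10 largest differences in each direction among proteins with a mean level at or above the median, the 10 most abundant proteins per tissue, the members of the rod and cone pairs, and names in 1 table only if among the 5 most abundant. Other list members appear as examples of their list. Some genes that these rules select, and 1 planned pair, are not reported here. Opsin, keratin, actin, creatine kinase, aldolase, ubiquitin and hemoglobin names are uncertain, since paralogs can share reads and short transcripts. Gene symbols of 335 of the 374 list genes were found in the RefSeq table of assembly mIctTri1.hap1, which was used for names only.

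The functions were tested on simulated data made from the retina reads for the comparison of eye against retina. Of 200 proteins changed among 12912, 100% of those changed 4-fold and 100% of those changed 2-fold came within 0.2 of the true log2 difference. Of the unchanged ones 0% passed 2-fold. Both simulated tissues had the same transcripts and lengths, with Poisson noise only. Separate assemblies, different fragments and reads counted on several transcripts were left out, so these figures do not measure the accuracy of the real comparison. Of 200 random lists of 15 proteins drawn from the real differences, 7.5% fell outside the central 95%, and with a shift of -0.6 in log2, 91.5% fell below it.

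The alternatives tried were no filter, a filter at 10 RPKM, median-ratio scaling, scaling to an equal total with and without the most abundant and mitochondrial proteins, pseudocounts of 0.1 and 5, best hits with an E-value of 1e-20 or lower, mammalian best hits, summed transcripts, other denominators and transcripts at 1 RPKM or more. Sums in RPKM, transcripts of 200 bases or more, length-weighted means and best-matching transcripts were added after seeing the data. Transcripts without a Swiss-Prot hit were not compared between tissues. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.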

Results

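RNA from whole eye and from isolated retina of the ground squirrel Ictidomys tridecemlineatus, a rodent active by day, was sequenced in 5 libraries, 2 of eye and 3 of retina. Per the labels, a library was prepared from the pooled RNA of 4 animals. The tables hold 1 value per transcript and tissue, so each difference between the tissues has no replicate check, and no p-value is given across genes. The scaling of the values corresponds to 264219334 reads for eye and 355988270 for retina. Levels are the RPKM of the highest transcript assigned to a Swiss-Prot protein, and differences are log2(eye + 1) minus log2(retina + 1), which understates the difference of low genes. For the 315 list members found in both tables, the 95% counting interval of this difference had a median half-width of 0.028 and was at most 0.15. These intervals cover counting error only.

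The first comparison asked which proteins' transcripts differed between eye and retina. Lens crystallins, corneal keratins and muscle proteins stood far higher in eye, while photoreceptor and synaptic transcripts were higher in retina, moderately so by the main measure. Among 13383 proteins present in both tables at 1 RPKM or more in either tissue, 1577 were at least 2-fold higher in eye and 482 at least 2-fold higher in retina. At 4-fold these numbers were 511 and 127. The other 11324 proteins, 84.6%, lay within 2-fold, and the median difference over all proteins was -0.0035. The split depended on the measure. With transcripts summed per protein and rescaled to an equal total, as the design was written before the data were examined, 344 proteins were at least 2-fold higher in eye and 1791 in retina, among 5568. The list medians were then -2.51 for cone, -2.00 for shared photoreceptor, -1.04 for rod and -2.35 for synapse members. The median of all proteins was -0.72. Sums left in RPKM gave 2296 proteins higher in eye and 2637 in retina, among 13696, with a median of -0.073. With the highest transcript rescaled to an equal total over proteins, 1138 were at least 2-fold higher in eye and 1051 in retina. The median of all proteins then moved to -0.29.

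**Figure D1:**
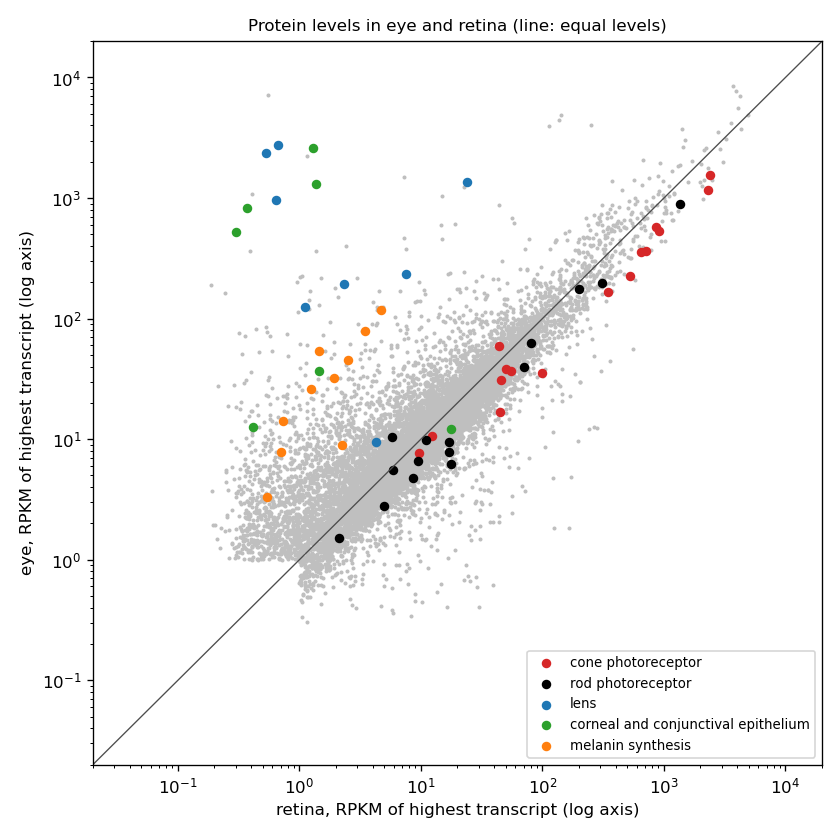
Level of each of 13383 proteins in retina (horizontal axis) and eye (vertical axis), in RPKM of the highest transcript on log axes, with members of 5 gene lists in colour and a line at equal levels. Lens, corneal and melanin members lie above the line except MUC5AC of the corneal list, and cone and rod members lie below it except OPN1SW and SLC24A1.

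Transcripts of retinal neurons were lower in whole eye than in retina. Of the 99 members of 7 lists (rod, cone, shared photoreceptor, bipolar, amacrine, ganglion, synapse) found in both tables, 96 were lower in eye and 3 higher, with a median difference of -0.65. All 16 cone members were measured and 15 were lower in eye, with a list median of -0.70. This stood at percentile 0.01 of 10000 random lists matched on level. OPN1MW and OPN1LW count as separate members, but neither symbol was found among the RefSeq names, so they may not be separate genes. Cone arrestin ARR3 stood at 1177 RPKM in eye and 2294 in retina, a difference of -0.96. PDE6H, the inhibitory subunit of the cone phosphodiesterase, was at 1541 and 2385 RPKM. The middle-wavelength opsin OPN1MW was at 535 and 914 RPKM, and GUCA1C, a calcium sensor of guanylate cyclase, at 580 and 857. The short-wavelength opsin OPN1SW was the exception, at 59.0 RPKM in eye and 43.9 in retina. Single differences depended on the transcript chosen: with best-matching transcripts ARR3 differed by 0.26, OPN1MW by 0.44 and PDE6H by -8.83, and with transcripts of 200 bases or more PDE6H differed by 0.33, GUCA1C by 0.17 and ARR3 by -2.08.

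Rod transcripts showed the same direction at lower levels. Of 15 rod members, 14 were lower in eye, with a median of -0.59 at percentile 0.01. Rod arrestin SAG was at 196 RPKM in eye and 310 in retina, and ROM1, a structural protein of outer segment discs, was at 62.7 and 80.2. The G protein subunit GNB1 was at 176 and 200 RPKM. PDE6G was at 890 and 1345 RPKM, values that came from transcripts of 135 and 131 bases. With best-matching transcripts ROM1 differed by -2.61, against -0.35 with the highest. The rod exchanger SLC24A1 was higher in eye, at 10.4 against 5.78 RPKM. All 17 members in both tables of the list shared by rods and cones were lower in eye, with a median of -0.69 at percentile 0. They included recoverin, RCVRN, at 973 and 2103 RPKM, GUCA1A at 1368 and 1593, UNC119 at 506 and 784, and the retinoid carrier RBP3 at 471 and 761. With best-matching transcripts RCVRN differed by -4.25, RBP3 by -3.25 and GUCA1A by -3.01, against -1.11, -0.69 and -0.22 with the highest, and GUCA1A differed by 1.15 with transcripts of 200 bases or more. GUCY2D, at 21.2 RPKM, was in the retina table only.

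Inner retinal lists also lay below the random lists. All 12 amacrine members were lower in eye, with a median of -0.72 at percentile 0, among them calbindin 2, CALB2, at 180 and 266 RPKM, GAD1 at 46.0 and 92.7, and the glycine transporter SLC6A9 at 42.6 and 50.2. All 12 bipolar members found were lower, with a median of -0.51 at percentile 0.18. PCP2 was at 125 and 234 RPKM, OTX2 at 51.7 and 77.8, and CABP5 differed by only -0.025. With length-weighted means the bipolar median was -0.13, inside the random lists, and PCP2 and CABP5 each differed by 0.07. Of 14 ganglion cell members 13 were lower in eye, with a median of -0.43 at percentile 0.48. The neurofilament NEFL was at 131 and 217 RPKM, SNCG at 184 and 214 (a difference of -0.22, or -2.28 with best-matching transcripts), THY1 at 148 and 170, and NEFH at 60.2 and 121. Of 5 horizontal cell members 4 were lower, with a median of -0.69 at percentile 0.17, with CALB1 at 65.8 and 107 RPKM and ONECUT1 at 1.46 and 10.8. All 13 synapse and ribbon members were lower, with a median of -0.73 at percentile 0.01. SNAP25 was at 437 and 1027 RPKM, CPLX3 at 221 and 368, CPLX4 at 249 and 295, and the vesicular glutamate transporter SLC17A7 at 195 and 335. With length-weighted means SNAP25 differed by 0.32 and CPLX4 by 0.09, and with best-matching transcripts CPLX4 differed by 2.22.

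**Figure D2:**
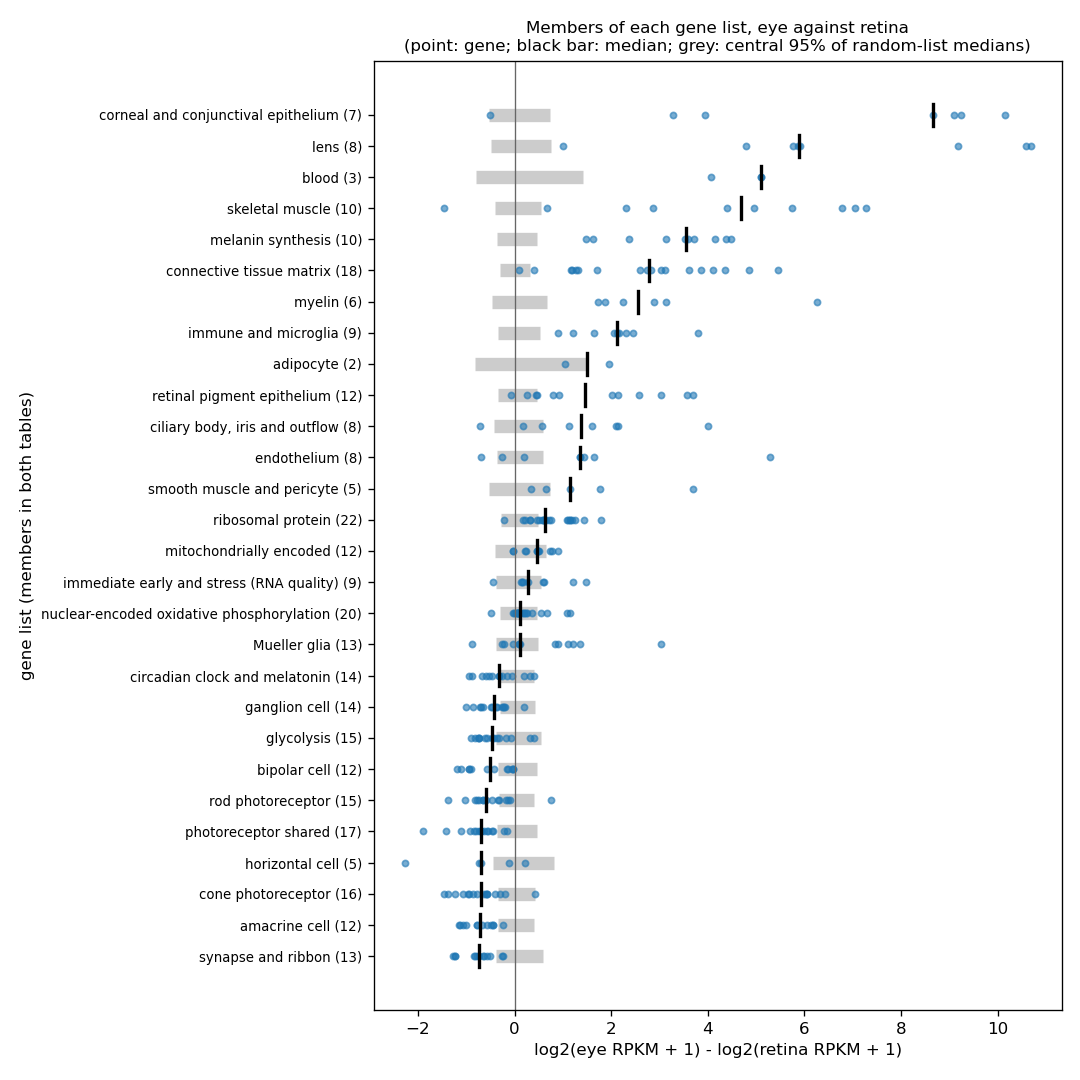
Difference between eye and retina on the log2(RPKM + 1) scale for each measured member (point) of 28 gene lists, with the list median (black bar) and the central 95% of medians of random lists (grey). The 7 lists of retinal neurons and synapses lie left of 0 and the lens and corneal lists farthest right, with medians of 5.88 and 8.66.

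Lens and corneal transcripts stood far higher in eye. Of 21 lens members, 8 were found in both tables, all higher in eye, with a median of 5.88 at percentile 100, and 12 were in the eye table only. The remaining member, CRYGS, was not found under the name fixed for it and stands in the tables as CRBS, at 2235 and 1.15 RPKM. Alpha-crystallin CRYAA, a chaperone of lens fibre cells, was at 2350 RPKM in eye and 0.53 in retina, CRYBB2 at 2743 and 0.667, and CRYAB at 1365 and 24.1. CRYBA2, at 1080 RPKM, was in the eye table only. Of 15 corneal and conjunctival members, 7 were in both tables and 8 in the eye table only. Of the 7, 6 were higher in eye, with a median of 8.66 at percentile 100. This median was 5.69 with strict E-values, 3.95 with transcripts of 200 bases or more and 3.54 with best-matching transcripts. The corneal keratin KRT12 was at 2594 and 1.29 RPKM, KRT19 at 1298 and 1.38, and KRT15 at 835 and 0.372. KRT13, at 1266 RPKM, was in the eye table only, and the mucin MUC5AC was lower in eye, at 12.1 against 17.6 RPKM, but differed by 0.47 with sums as designed. Short keratin transcripts may share sequence, which leaves levels of single keratins uncertain.

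Lists of pigmented, connective and muscle tissue were likewise higher in eye. All 10 melanin members were at least 2-fold higher, with a median of 3.55 at percentile 100, including TYRP1 at 117 and 4.72 RPKM, PMEL at 79.2 and 3.49, MLANA at 54.3 and 1.46, and DCT at 45.3 and 2.5. Of 12 retinal pigment epithelium members 11 were higher in eye and 6 at least 2-fold, with a median of 1.46 at percentile 100. With best-matching transcripts 9 were higher in eye and the median was 0.60, at percentile 99.5. The isomerase RPE65 was at 238 and 17.5 RPKM, transthyretin TTR at 682 and 56.2, RGR at 412 and 218, and RRH at 92.5 and 67.7. With best-matching transcripts MLANA differed by -0.67, TTR by -2.36 and RGR by -0.78, and with sums as designed RRH differed by -0.026. All 18 connective tissue members in both tables were higher in eye, 16 of them at least 2-fold, with a median of 2.78 at percentile 100. Decorin, DCN, was at 376 and 7.55 RPKM, SPARC at 205 and 83.9, FMOD at 79.1 and 3.61, and BGN at 72.7 and 1.56. Of 21 skeletal muscle members, 11 were in the eye table only. Of the 10 shared members 9 were higher in eye, with a median of 4.68 at percentile 100, such as the myosin light chain MYLPF at 366 and 1.37 RPKM and troponin TNNI2 at 220 and 1.01. ACTA1 was at 952 and 601 RPKM, and differed by -0.62 with best-matching transcripts. CKM was lower in eye, at 210 against 584 RPKM, with a retina transcript of 115 bases, and differed by 1.02 with transcripts of 200 bases or more. Actins and creatine kinases have close paralogs, and reads may be shared between them. With sums as designed the medians were 2.07 for 4 melanin members, 1.40 for 7 connective tissue members and 1.99 for 10 skeletal muscle members. These lists stayed above the random lists.

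The remaining tissue lists were smaller. The ciliary body, iris and outflow list had 7 of 8 members higher in eye, with a median of 1.37 at percentile 99.95. The prostaglandin synthase PTGDS was at 4065 and 251 RPKM, AQP1 at 150 and 34.1, and CA2 was lower in eye at 130 against 216. With best-matching transcripts PTGDS differed by 0.55, against 4.01 with the highest. Myocilin, MYOC, at 105 RPKM, was in the eye table only. All 5 smooth muscle and pericyte members in both tables were higher in eye, with a median of 1.15 at percentile 99.4, including ACTA2 at 257 and 74.9 RPKM and MYH11 at 25.8 and 1.06. Desmin, DES, at 60.5 RPKM, was in the eye table only. Of 8 endothelial members 6 were higher in eye, with a median of 1.35 at percentile 99.9, but the median was -0.26 with the filter at 10 RPKM, which kept 3 members, and -1.61 with sums as designed. PLVAP was at 50.9 and 0.336 RPKM, while ESAM was at 47.2 and 56.8 and KDR at 18.1 and 29.8. All 3 measured blood members were higher in eye, with a median of 5.09 at percentile 99.8, with hemoglobin HBB at 4897 and 142 RPKM, HBA at 3942 and 113, and ALAS2 at 34.2 and 1.11. All 9 immune members in both tables were higher in eye, with a median of 2.13 at percentile 100, with CD74 at 64.3 and 14 RPKM and C1QB at 21.8 and 3.19. CSF1R, a receptor of macrophages and microglia, was in the retina table only, at 5.74 RPKM. All 6 myelin members in both tables were higher in eye, with a median of 2.57 at percentile 100, with MBP at 170 and 1.23 RPKM and CNP at 37.0 and 10.5. The 2 adipocyte members in both tables, LIPE and CIDEC, had a median of 1.5 at percentile 97.4, inside the central 95% of random lists.

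Housekeeping lists had smaller medians than the lens, corneal and skeletal muscle lists, but not smaller than all lists of retinal neurons. Ribosomal proteins were higher in eye for 21 of 22 members, with a median of 0.64 at percentile 99.4, with RPS18 at 816 and 358 RPKM and RPLP0 at 1253 and 1108. RPLP0 changed sign when both tissues were scaled to an equal total. Glycolytic transcripts were lower in eye for 13 of 15 members, with a median of -0.47 at percentile 0.89, such as ALDOC at 1418 and 2492 RPKM and GAPDH at 2563 and 2878. LDHA, at 660 and 531 RPKM, was higher in eye, but not after scaling to an equal total (-0.017). Of 14 circadian members 11 were lower in eye, with a median of -0.32 at percentile 2.22, including NR1D1 at 79.3 and 153 RPKM and DBP at 131 and 157, though DBP differed by 0.24 with transcripts of 200 bases or more. The lists of mitochondrially encoded transcripts (median 0.47, percentile 91.6), Mueller glia (0.10, 64.3), nuclear-encoded oxidative phosphorylation (0.12, 60.1) and immediate early and stress genes (0.27, 86.8) lay inside the central 95%. The Mueller glia and oxidative phosphorylation medians were -0.23 and -0.21 after scaling to an equal total, and that of the immediate early and stress genes was -0.056. With sums as designed the 3 medians were -0.41, -0.65 and -1.67, the last from 2 members, and with transcripts of 200 bases or more the Mueller glia list lay above the random lists, with a median of 0.84. Of its 13 members 9 were higher in eye, 4 of them at least 2-fold, and 6 were higher after scaling to an equal total, 2 of them at least 2-fold. Within the glial list GFAP, an intermediate filament of astrocytes and reactive glia, was at 145 RPKM in eye and 16.9 in retina, APOE at 1160 and 453, and GLUL at 856 and 801, a difference that changed sign with that scaling. With best-matching transcripts APOE differed by -1.18 and GLUL by -0.73.

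In all, 13 of the 28 lists lay above the central 95% of random lists and 10 below it. With transcripts summed and rescaled as designed, 11 lay above and 4 below, and no list changed side. The rod, bipolar, horizontal, ganglion, glycolysis and circadian lists were then no longer below, and the endothelial and immune lists no longer above. The median of all proteins was then -0.72, and list medians lay lower with it, at -1.04 for 8 rod members, -1.04 for 7 bipolar members, -0.75 for 9 ganglion cell members, -1.40 for 15 glycolytic members and -0.88 for 10 circadian members. The horizontal and immune lists kept 1 member each, at -0.98 and 1.85. With best-matching transcripts the ciliary body, glycolysis, circadian and ribosomal lists lost their calls and the mitochondrially encoded list lay below, with a median of -2.60. The circadian call was also lost with the filter at 10 RPKM, median-ratio scaling, pseudocount 0.1 and mammalian hits, that of the bipolar list with length-weighted means, and those of the horizontal and endothelial lists with the filter at 10 RPKM. The adipocyte list lay above the random lists with mammalian hits, transcripts of 200 bases or more and best-matching transcripts.

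The proteins with the largest differences were chosen by size alone, among those with a mean level at or above the median. Of the 10 highest in eye, 4 were crystallins or their close relatives under the names CRBB2, CRYAA, CRBS and CRBA1, and 5 were keratins, under the names K1C12, K1C24, K1C15, K1C19 and K2C5. The largest difference, 12.17, belonged to Y114, an uncharacterised bacterial protein name at 7134 RPKM in eye on a transcript of 147 bases. The 10 highest in retina were TRHDE, an ectoenzyme that degrades thyrotropin-releasing hormone, at 164 RPKM against 1.83 in eye, the transcription factor E2F3 (126 against 1.84), the zinc finger protein DPF1 (173 against 4.89), IG2R (39.3 against 0.617), DOPD (30.2 against 0.409), the receptor GP179 (122 against 4.75), the SUMO ligase PIAS4 (281 against 12.3), histone H3 (266 against 12.5), the phospholipase PA24B (28.9 against 0.592) and TRIM8 (243 against 12.1). With the best-matching transcript of each protein instead of the highest, 9 of the 10 eye proteins and 5 of the 10 retina proteins kept a 2-fold difference. Of these 5, DPF1, IG2R and TRIM8 had 1 transcript in retina, so that their retina value could not change. Sizes changed unevenly among the 9 eye proteins. K1C24 fell from 9.58 to 1.83 and K1C19 from 9.09 to 3.30, while K2C5 went from 8.66 to 8.41. Of 136 list members and named proteins with at least a 2-fold difference, 104 kept it with best-matching transcripts, 21 came under 2-fold and 11 changed sign.

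The next question was what made up each tissue's transcripts. The most abundant names in both tissues included mitochondrially encoded ATP6, at 6960 RPKM in eye and 4209 in retina, COX3 at 5583 and 4043, and COX2 at 4220 and 3566. COX2 changed sign after scaling to an equal total, and COX3 differed by -0.11 with transcripts of 200 bases or more. Polyubiquitin, UBIQP, was at 4851 and 4946 RPKM, and differed by 0.07 with that length limit. ART2 and RRT15, names that lie within ribosomal DNA in yeast, were at 8475 and 7681 RPKM in eye and 3710 and 3912 in retina. The 10 highest in eye also held Y114, HBB, ISCU and PTGDS, of which ISCU, at 4400 RPKM against 136 in retina, came from a transcript of 334 bases. The 10 highest in retina also held UBIQ, RL40, creatine kinase KCRB at 3039 RPKM and G3P. With best-matching transcripts ATP6 differed by 11.49, COX3 by 4.00 and COX2 by 3.68, against 0.73, 0.47 and 0.24 with the highest. ISCU then differed by 0.19, against 5.00, and KCRB by 1.31, UBIQ by 4.34 and RL40 by 0.031, against -0.62, -0.20 and -0.09 with the highest. Of names found in the eye table only, the highest were TE53, HBA1, HBB1, HBA2 and UBB, and in the retina table only ALDCB, TBA1A, TBA2, EF1AC and NDK. As shares of the level summed over proteins, cone transcripts made up 0.931% in eye and 2.05% in retina, rod transcripts 0.257% and 0.477%, lens transcripts 1.87% and 0.0093%, corneal transcripts 1.51% and 0.00517%, and glycolytic transcripts 1.94% and 3.28%. With transcripts summed these shares were 1.80% and 8.54% for cone transcripts, 0.0054% and 0.0362% for rod, 6.71% and 0.0003% for lens, 3.63% and 0.0000975% for corneal and 8.88% and 22.9% for glycolytic transcripts. With all transcripts as the denominator the cone shares were 0.00514% and 0.0177%. These are shares of RPKM and not of reads.

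Cone transcripts exceeded their rod counterparts in retina for all 4 pairs of phototransduction proteins reported, a comparison within 1 table. Cone transducin GNAT2 was 29.7 times rod transducin GNAT1 (95% counting interval 29.0 to 30.5), at 531 and 17.8 RPKM. The channel subunit CNGA3 was 21.1 times CNGA1 (20.2 to 22), at 45.1 and 2.14 RPKM. Cone arrestin ARR3 was 7.41 times SAG (7.36 to 7.46), and PDE6C was 3.88 times PDE6A and PDE6B together (3.83 to 3.93). In eye the same ratios were 35.8, 11.1, 6.01 and 2.48. The level is the highest over unequal numbers of transcripts, in retina 1138 for ARR3 against 27 for SAG, and 36 for GNAT2 against 4 for GNAT1. Over retina proteins the Spearman correlation of transcript number with level was 0.44. The counting intervals do not cover this. The cone member was higher in all 4 pairs under each of the 6 other settings tried, but the sizes moved: with summed transcripts the retina ratio was 272 for transducin and 317 for arrestin, and with the best-matching transcript 1.46 for arrestin.

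**Figure D3:**
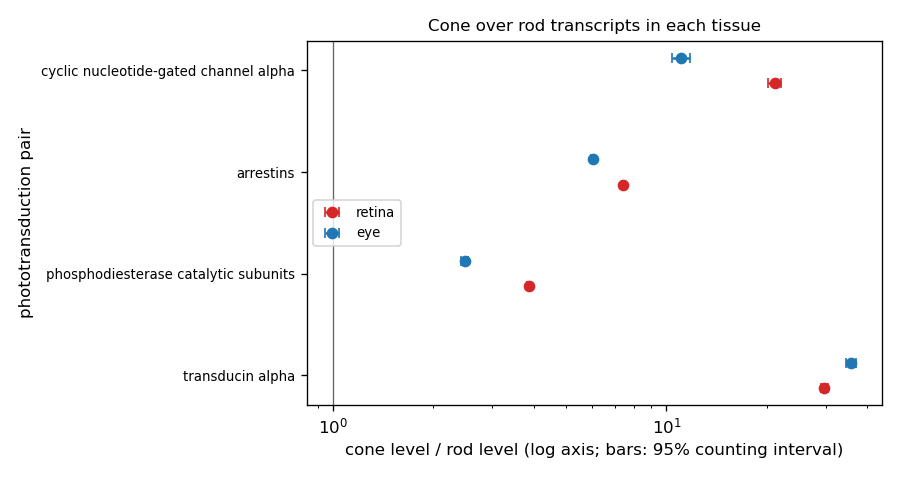
Cone level divided by rod level for 4 pairs of phototransduction proteins in retina and eye, on a log axis with a line at equal levels and bars for the 95% counting interval. All 8 ratios lie above the line, from 2.48 for phosphodiesterase in eye to 35.8 for transducin in eye.

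The tables covered different numbers of transcripts. The eye table held 165650 transcripts, of which 61797, 37.3%, had a Swiss-Prot hit, and that of retina held 214063, of which 62889, 29.4%, had one. The hits named 15287 proteins in eye and 14600 in retina, with 13949 in both. A further 1338 names were in the eye table only and 651 in the retina table only. A name can be missing from an assembly because the tissue lacks its transcripts, through depth, or because they were assigned to a related name. These reasons were not told apart. Among list members, 12 of lens, 8 of cornea and conjunctiva and 11 of skeletal muscle were in the eye table only, and 0 in the retina table only. Retina, with the larger read total, lacked more names. Some names in 1 table only had many reads there, such as UBB with 326418 in eye and TBA1A with 658223 in retina. Of the 374 list genes, 359 were found in at least 1 table under the names fixed beforehand, and the others may stand under other names.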

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

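Transcripts without a Swiss-Prot hit entered no comparison. Every transcript listed had a value above 0, so the level that 3 reads would give is printed for scale only. The most abundant of them stood at 21662 RPKM in eye, on a transcript of 220 bases, where 3 reads would give 0.0516 RPKM, and at 15737 RPKM in retina, on one of 143 bases, where 3 reads would give 0.0589. In eye 735 transcripts of 1000 bases or more without a hit stood at 10 RPKM or more, and in retina 1167 did. All 100 of the most abundant transcripts in each table had no hit. Transcripts without a hit held 71.9% of the summed RPKM in eye and 67.1% in retina. No explanation for these transcripts was tested.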

How the results depend on the processing

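No paired analysis was possible because the tables hold one pooled value per tissue. For the same reason leaving out each library, the replicate block and the count models planned as alternatives were not run. Of 82 alternative values of the main counts, 67 stayed within 1.5 times and 15 did not. All 4 cone and rod pairs kept their direction in both tissues, no list called on one side was called on the other, and proteins in both tables numbered 13659 with strict E-values and 12356 at 1 RPKM or more.

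Proteins at least 2-fold higher in eye, 1577 in the main setting, numbered 921 with the filter at 10 RPKM, which left fewer proteins, 815 with pseudocount 5, which shrinks low proteins, and 344 with transcripts summed and rescaled as designed. Those higher in retina, 482 in the main setting, numbered 1051 and 871 with the scalings to an equal total, with and without the most abundant proteins, which multiply the levels of a tissue by a common factor, 265 with pseudocount 5, 1791 with sums as designed, 2637 with sums in RPKM and 272 with length-weighted means. Lists below the random lists, 10 in the main setting, numbered 4 with sums as designed, where the adipocyte list had no member left, and 4 with sums in RPKM. Of the 10 most abundant eye proteins, 5 were shared with sums as designed, 6 with length-weighted means and 4 with best-matching transcripts, as were 4 of the 10 in retina. The cause was not tested for the sums, length-weighted means and best-matching transcripts. Sums in RPKM, length-weighted means, best-matching transcripts and the limit of 200 bases were chosen after seeing the data.

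The endothelial median, 1.35, was -0.26 with the filter at 10 RPKM, which kept fewer members, and -1.61 with sums as designed. Among list members and the proteins named for their size or abundance, differences of at least 2-fold reversed with best-matching transcripts for E2F3 (0.11), PIAS4 (0.58), H3 (0.0012), APOE (-1.18), TTHY (-2.36), MAR1 (-0.67), KCRM (0.41), OPT (-1.24), RL8 (-0.59), RS6 (-0.46) and RS8 (-0.18), with sums as designed for CAH14 (-0.41) and WFDC1 (-0.61), and with sums in RPKM for WFDC1 (-0.27) and FBN1 (-0.038). H3 was 0.26 with strict E-values and with transcripts of 200 bases or more, KCRM was 1.02 in both of these and with mammalian hits, and SNP25 was 0.32 with length-weighted means. The cause was not tested for these. Of 4537 values of these 335 proteins, 2425 stayed within the counting interval and 1884 moved beyond it with the same sign. Those that changed sign from a main difference under 2-fold numbered 208, in 94 of 199 such proteins, 35 of them with best-matching transcripts and 33 with scaling to an equal total. The 2425 include all values with no filter, the filter at 10 RPKM and median-ratio scaling, which leave a single difference unchanged or nearly so. In the other settings, those that stayed ran from 0 of 335 with scaling to an equal total to 313 of 327 with mammalian hits. With best-matching transcripts 137 of 334 stayed. Of 391 list medians 215 moved beyond the counting half-width of their members, and of 392 list shares 350 moved. Counting intervals were narrow for proteins in both tables, but a name in 1 table only may reflect the tissue, depth or naming. The spread between libraries is unknown.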

Other observations

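All tests of explanations below were chosen after the results had been seen.

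Myelin transcripts were higher in eye, while Mueller glial transcripts went both ways. MOBP, at 56.7 RPKM, was in the eye table only, and PMP22 was at 31.8 RPKM in eye and 2.71 in retina. Of 13 Mueller glial members 9 were higher in eye, and 6 after scaling to an equal total. At least 2-fold higher were GFAP (3.03), APOE (1.35, but -1.18 with best-matching transcripts), VIM (1.21, but 0.79 with best-matching transcripts) and CA14 (1.10, but -0.41 with sums as designed). RLBP1, a retinoid carrier of Mueller glia, was at 347 and 323 RPKM, a difference that changed sign with scaling to an equal total, and the glutamate transporter SLC1A3, 1 of 4 members lower in eye, was at 84.2 and 156. Among clock genes, PER1 and PER2 were slightly higher in eye, by 0.19 and 0.33 (PER1 by -0.11 after scaling to an equal total), while PER3 differed by -0.88 and BMAL1, under the symbol ARNTL, by -0.67. AANAT, the penultimate enzyme of melatonin synthesis, was at 15.1 and 23.4 RPKM. PER2, PER3 and AANAT differed by -0.21, 0.20 and -2.45 with best-matching transcripts.

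Transcripts of retinal neurons were lower in eye. Scaling by the authors would move all proteins, but the median over all 13383 was -0.0035. This argues against it as the cause for the main measure only. The median was -0.29 with scaling to an equal total and -0.72 with sums as designed. Different fragmentation in the separate assemblies would leave members with transcripts of like length near 0, but the 35 members with lengths within 10% had a median of -0.47, which argues against it as the whole cause. Retina is 1 part of the eye, and a candidate explanation is that its transcripts are diluted alike. The medians of the 7 lists spanned 0.31, at percentile 46.7 of spans with the 99 members shuffled between the lists. Equal dilution would give a span typical of the shuffled ones, but so would any cause that acts on all 7 lists alike. The span therefore cannot decide, and a tissue difference stays open.

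Pigment epithelium and melanin transcripts were also present in retina. Whole-eye RNA carried into the retina libraries would bring lens and corneal transcripts at the same fraction. A further 12 lens and 8 corneal members were in the eye table only and have no fraction, so one over all members may be lower. MUC5AC, in both tables, was higher in retina, which carried RNA would not give. The 15 lens and corneal members in both tables stood at a median of 0.891% of their eye level, against 35.6% for pigment epithelium members. This argues against carried RNA as the source for the pigment epithelium list as a whole. Its members ranged from 7.33% for RPE65 and 8.24% for TTR to 83.2% for RDH10 and 105% for BEST1. For the lowest members the source stays open. Melanin members stood at 5.35%, the lens and corneal fraction being 0.167 times this. It was lower in every setting, at 0.0082 times with sums as designed and 0.235 times with best-matching transcripts. At these medians carried RNA would give a part of the melanin level and not the whole, and a part stays open. Pigment epithelium cells attached to the isolated retina may contribute. The fraction for pigment epithelium members was 6.66 times that for melanin members, and melanocytes of iris and choroid, which add melanin transcripts to eye alone, keep this open.

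The largest differences of single proteins could rest on 1 unrepresentative transcript. Of the 10 retina proteins, 7 had more than 1 transcript in retina, and with the best-matching transcript 2 of these 7 kept a 2-fold difference, DOPD (-3.62) and PA24B (-3.95), which fits this explanation for the 7 as a set. DPF1, IG2R and TRIM8 had 1 transcript in retina and could not be tested. Of the 10 eye proteins, which all had more than 1 transcript in eye, 9 kept it and Y114, at 0.81, did not. K1C24 was among the 9 but fell from 9.58 to 1.83. The explanation stays open for the eye proteins. The proteins were chosen for large differences, and another transcript would be expected to give smaller ones.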
